A study of Rattus norvegicus with 6 samples.

How the data were processed

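Expression was measured in metrial gland of pregnant rats at gestation day 13.5. The metrial gland is the part of the uterine wall behind the placenta, where maternal natural killer cells, vessels and decidual stroma meet invading trophoblast. Per the labels, 3 arrays came from ambient animals kept at 21% oxygen and 3 from animals kept at 10.5% oxygen (hypoxia), an exposure that began on day 6.5 and ended on day 13.5 of gestation. Total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised to a single-channel Affymetrix rat array, per the labels' protocols. The labels do not say that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

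The deposited values are log2 expression summaries, 1 per probe set and array. That the scale is log2 was read from the values, which lie between 2.98 and 14.9 on every array. The submitters' processing notes name MAS5 and Affymetrix Expression Console, with no role or version for either. The background correction, the summarization and the scaling between arrays are not given in the sources used here. The medians of the 6 arrays lay between 6.44 and 6.48 and the upper quartiles between 8.31 and 8.40, so the authors' values already shared a common scale. A method that gives all arrays the same distribution hides a change that moves most genes at once, and the choice of summary sets how far low signals are compressed. The planned test had assumed linear MAS5 signal. Values already on a log2 scale were to be used as they were, and this was done.

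The array held 31099 probe sets. After 57 control probe sets were left out, 31042 remained. The 40% with the lowest mean over all 6 arrays were also left out, which removed 12417 probe sets with a mean below 5.74 and kept 18625. Of the 31042 probe sets, 20826 carried 1 gene symbol in the platform annotation, 436 several and 9780 none. Symbols were looked up through the gene identifier in the RefSeq gene table of assembly GRCr8, which held 20758 of the 20826 and changed none of them. Probe sets with several symbols were tested but give no gene name. For a gene with several kept probe sets, the one with the highest mean over all arrays was used, and the text says where another probe set differed in sign or in passing the threshold. Probe sets of the prolactin family and of the globins can bind transcripts of close paralogs, so values of single members are uncertain.

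Hypoxia was compared with ambient in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with a mean-variance trend and group as the only term. Tests were two-sided with Benjamini-Hochberg adjustment over the kept probe sets, and the threshold was an adjusted p of 0.05. Adjusted p-values without another name come from this test, with n = 3 arrays per group. Changes are log2 differences, hypoxia minus ambient, with their standard error (SE), and group levels are means with SD. Gene lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists. Measured genes are those with a kept probe set. Of the genes on the array these were 11 of 18 for T and B cells and 11 of 20 for epithelium. They were 14 of 21 for the erythroid and blood list and 6 of 18 for yolk sac and fetal liver. Camera with a correlation estimated from the data, and fry, were run beside it. Fry asks whether the genes of a list move, on balance, one way, without comparing them with other genes. Counts of list members are given over all probe sets tested and adjusted over the list alone.

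Arrays carry no read depth, and their number limits the precision. As a guide to background, 27 probe sets for bacterial transcripts were used, whose median per array lay between 3.65 and 3.73 and whose highest value on any array was 5.00. A gene at or below the highest of these on all 3 arrays of a group has only a bound there. Its fold is then given as "at least", against the mean of that highest bacterial value per array. No pair of arrays held identical values. Correlations between arrays of a group lay between 0.989 and 0.993 over the kept probe sets, and those between groups between 0.974 and 0.983.

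The groups, the test, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls past the threshold among genes whose groups did not overlap and whose higher group mean reached the median of all probe sets (6.45). It also took up to 4 members of each list past the threshold, by smallest p, or 2 members where none passed, and a fixed set of genes. It gave 108 genes. Hba1, in the fixed set, had no probe set with a single symbol. Other genes are named where a count of 5 or fewer called for it or where they were singled out later, and these were chosen after their values were seen.

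The fit was tested on simulated data made from the ambient means and the residual spread of this comparison. That spread was first shrunk toward its trend with the mean, as the fit does. Each of 20 draws held 200 changed probe sets among 31042, with 18625 tested. The fit recovered 83.4% of 1.5-fold, 93.2% of 2-fold and 88.9% of 4-fold changes, and 6.75% of its calls were false. The missed 4-fold changes were the 11.1% that fell below the filter on low means. A simulated shift of the natural killer cell list was called in 10 of 10 draws, and in 0 of the draws without a shift. Genes were simulated as independent, which these tissues' genes are not, and with the normal noise that the fit assumes. These rates may thus be optimistic.

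The alternatives were quantile normalization, centring on array medians, an offset of 16 or 64 added to the linear signal, no filter, a 60% filter, no variance trend, a robust trend, array weights, the replicate number as a block, and each array left out in turn. For lists, the mean over a gene's probe sets, the estimated correlation and fry were added, and for the count of probe sets an adjusted p of 0.10. No file of the series was left unused. Genome positions are not reported, since the array values name no genome build.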

Results

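Metrial gland RNA from 6 arrays was compared, 3 from rats in ambient air (21% oxygen) and 3 from rats held at 10.5% oxygen over gestation days 6.5 to 13.5. The comparison asks which transcripts of this maternal-fetal tissue differ after a week of low oxygen around the time when trophoblast enters the uterine wall. Across the kept probe sets the first principal component held 55.8% of the variance and separated the 2 groups, and the second held 14.7%.

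Low oxygen went with higher expression of trophoblast, placental prolactin, endothelial and red cell genes, and with lower expression of lymphocyte and epithelial genes, as lists tested with a preset correlation. With an estimated correlation 0 of the 26 lists passed by camera (lowest adjusted p = 0.15, with 5 lists at an unadjusted p under 0.05). The largest rise was that of Trh, which encodes the precursor of thyrotropin-releasing hormone. It rose by 4.96 (SE 0.75), from 8.18 ± 1.83 to 13.14 ± 0.19 (SD, n = 3 each), or 31.0-fold, with a limma adjusted p of 0.0136. The rise was 6.00 without ambient replicate 1 and 4.28 without ambient replicate 2, and the call was lost without ambient replicate 3 (adjusted p = 0.0597; range over the alternatives 1.35e-04 to 0.0597). The largest fall was that of 1810009J06Rikl, a gene of uncharacterised function, by -3.33 (SE 0.41), or 10.1-fold. In all, 749 probe sets were higher and 367 lower in hypoxia at an adjusted p under 0.05, 1116 of 18625 tested. They covered 515 genes that were higher and 286 that were lower, with 0 genes called in both directions and 4422 probe sets at an unadjusted p under 0.05. At least 1.5-fold differences were seen in 331 higher and 117 lower probe sets, and at least 2-fold in 140 and 27. The 331 fell to 175 without ambient replicate 3 and 201 without ambient replicate 2, and the 117 to 27 without ambient replicate 3, 44 without hypoxia replicate 2 and 61 without ambient replicate 2. The 27 lower by at least 2-fold fell to 5 without hypoxia replicate 2, 10 without ambient replicate 3, 11 without ambient replicate 1 and 14 without ambient replicate 2. All 1116 called probe sets had groups that did not overlap, as did 29.9% of the probe sets tested, against 10% by chance for 3 against 3. Quantile normalization moved the share of calls that were higher from 67.1% to 55.4%. With 1 array left out, the count was 270 without ambient replicate 3, 353 without ambient replicate 2 and 434 without hypoxia replicate 1. It was 474 without hypoxia replicate 2, 536 without ambient replicate 1 and 1006 without hypoxia replicate 3, so the fall depended on which array was left out. The 3' minus 5' signal of the beta-actin control, a sign of RNA integrity, was 0.50 ± 0.07 in ambient and 0.67 ± 0.10 in hypoxia (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give), and that of GAPDH was -0.03 ± 0.02 and 0.00 ± 0.05 (exact permutation p = 0.2).

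The other large rises took in genes of several kinds. Alox15, a lipoxygenase of arachidonic acid metabolism, rose by 3.27 (SE 0.29), Lmcd1, a LIM domain protein, by 2.56 (SE 0.20), and Cd52, a surface glycoprotein best known from leukocytes, by 2.63 (SE 0.20). Cd52 and Rbp7 stood above every bacterial control on 2 of the 3 ambient arrays. Elovl2, which lengthens polyunsaturated fatty acids, lay at bacterial control level in ambient and was at least 8.48-fold higher in hypoxia. Orm1, an acute phase protein, rose by 3.11 (SE 0.59), Rbp7, a retinol-binding protein, by 2.55 (SE 0.23), and Sslp1l1 by 3.63 (SE 0.51). Among the falls, Pla2g2a, a secreted phospholipase, fell by -1.76 (SE 0.17), from 11.02 ± 0.17 to 9.26 ± 0.37. Wfdc10a fell by -1.85 (SE 0.15), C4bpa, a complement regulator, by -1.67 (SE 0.24), and Vcam1, an adhesion molecule for leukocytes, by -1.23 (SE 0.25). Lrat, which stores retinol as esters, fell by -1.69 (SE 0.32), and the water channel Aqp8 by -1.70 (SE 0.38). The calls of Vcam1, Lrat and Aqp8 were lost without any 1 ambient array or hypoxia replicate 2 (adjusted p up to 0.118, 0.0877 and 0.137), that of Vcam1 also without hypoxia replicate 1, that of Lrat without hypoxia replicate 3 and that of Aqp8 with no variance trend (0.0547) or a robust trend (0.0676). The call of Orm1 was lost without any 1 array but ambient replicate 1 (up to 0.0962), without which its rise was 3.88, and with a robust trend (0.0602).

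**Figure D1:**
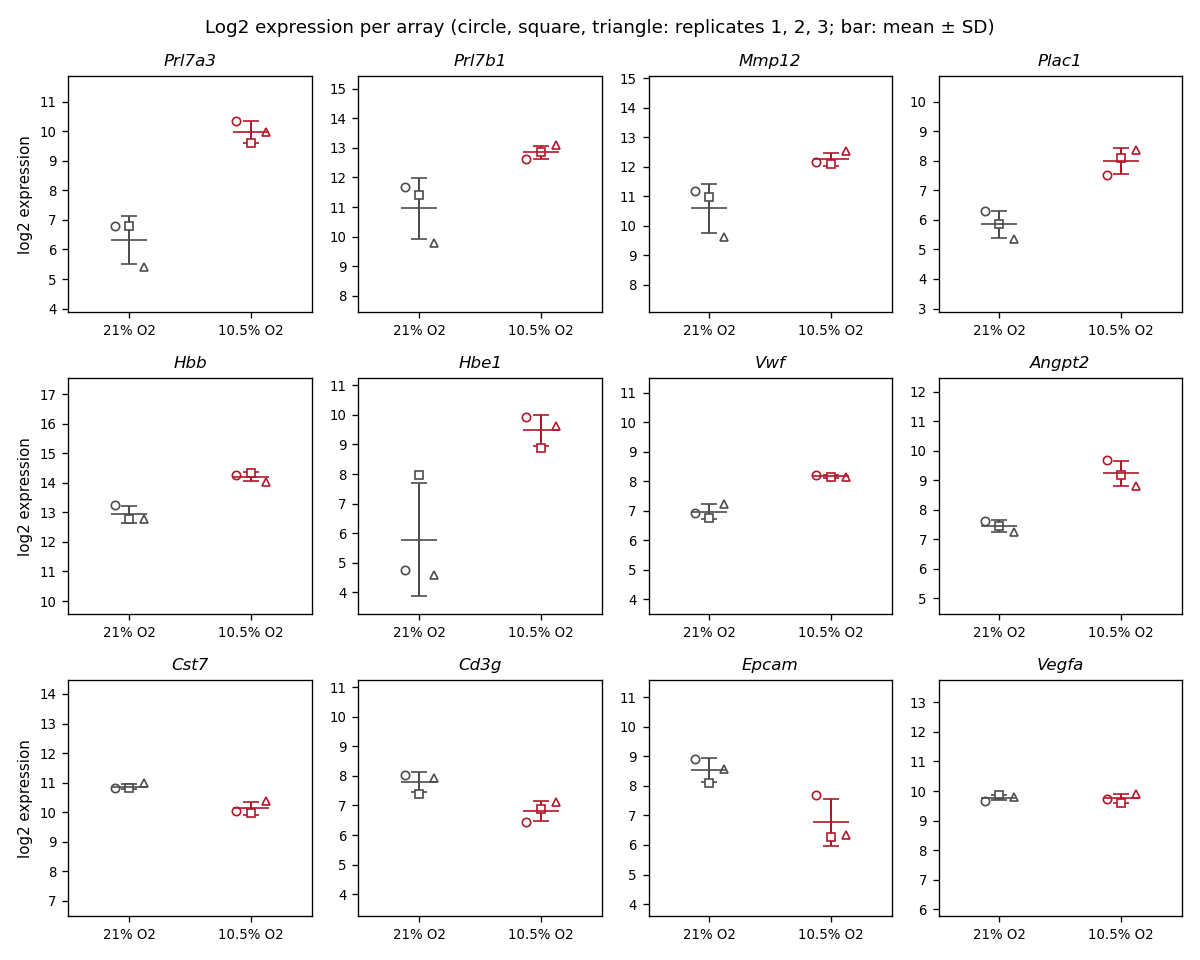
Log2 expression of 12 genes on each of the 6 arrays, ambient (21% oxygen, grey) and hypoxia (10.5% oxygen, red), with bars for the mean ± SD of 3 arrays; all panels span the same number of log2 units. Prl7a3 lay at 6.33 ± 0.81 in ambient and 9.98 ± 0.37 in hypoxia, Cst7 at 10.86 ± 0.09 and 10.13 ± 0.22, and Vegfa at 9.78 ± 0.10 and 9.75 ± 0.15.

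Placental prolactins, hormones made by trophoblast and decidual cells, rose as a group. Of 16 members on the array, 9 were measured after the filter on low means. Of these 9, 8 rose, 0 fell and 1 (Prl2a1, 1.85, adjusted p = 0.0512) did not pass. Adjusted over the list alone all 9 passed. Prl2a1 passed without ambient replicate 1 (2.23) or ambient replicate 3 (1.27), with median centring, an offset of 64 and the 60% filter (0.0438 to 0.049). Prl7a3 rose 12.5-fold, by 3.64 (SE 0.37), and Prl8a9 by 2.51 (SE 0.45). Prl5a1 and Prl7b1, known from invasive trophoblast of the rat metrial gland, rose by 1.93 (SE 0.40, adjusted p = 0.037) and 1.92 (SE 0.43, adjusted p = 0.0429). The list shifted upward against all other genes (median 1.93, camera adjusted p = 3.58e-07), a call that was lost with adjusted p = 0.295 with an estimated correlation. The calls of Prl5a1 and Prl7b1 were lost without ambient replicate 2 or any 1 hypoxia array, with adjusted p up to 0.0878 and 0.105, and with a robust trend (0.0748 and 0.0854), that of Prl7b1 also with no variance trend (0.0559). The call of Prl8a9 was lost without hypoxia replicate 1 (0.0776) or hypoxia replicate 3 (0.0506). On ambient replicate 3 these 4 genes lay lowest in their group, and without it the list's median rise was 1.39.

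Trophoblast markers moved with them. Of 23 measured, 10 rose, 1 fell (Eomes, which natural killer cells also express) and 12 did not pass; adjusted over the list alone, 18 were higher and 2, Eomes and Dlx3, lower. Plac1, a placenta-specific secreted protein, rose by 2.16 (SE 0.27), or 4.46-fold, Krt7 by 1.04 (SE 0.13) and Krt8 by 0.88 (SE 0.13). Cdkn1c, a cell cycle inhibitor, rose by 1.54 (SE 0.20) and Igf2, a fetal growth factor, by 1.58 (SE 0.21). Krt18 was higher by 0.87 with an adjusted p of 0.0566, and passed without ambient replicate 2 (0.0386) or with the replicate block (0.0444; range over the alternatives 0.0386 to 0.141). The list shifted upward (median 0.91, camera adjusted p = 6.14e-07; adjusted p = 0.295 with an estimated correlation). Among embryonic globins, Hbe2, left out for its low mean, differed by 0.16 (limma adjusted p without the filter 0.342). Higher in these hypoxia arrays were Hbe1 by 3.71 (SE 0.82), Hbg1 by 3.31 (SE 0.59) and Hbz by 2.50 (SE 0.58). Part of these differences is against background, since Hbe1 and Hbg1 stood above every bacterial control on 1 of the 3 ambient arrays, replicate 2, and Hbz on 2. Hbe1 was at 7.98 on ambient replicate 2 and at 4.76 and 4.58 on the others, and its call and that of Hbz were lost without any 1 array but that one (adjusted p up to 0.134 and 0.145), with no variance trend, with a robust trend and with array weights. Without ambient replicate 2 the differences of Hbe1, Hbg1 and Hbz were 4.81, 4.05 and 3.26, and without ambient replicate 3 that of Hbe1 was 3.11. The call of Hbg1 was lost without ambient replicate 1, ambient replicate 3 or hypoxia replicate 1 (up to 0.0845), and that of Krt8 without ambient replicate 3 (0.0588).

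Matrix metalloproteinases and their inhibitors shifted upward (median 0.18, camera adjusted p = 7.39e-04; adjusted p = 0.15 with an estimated correlation). Of 18 measured, 3 rose, 0 fell and 15 did not pass; adjusted over the list alone 7 were higher. Mmp10, a stromelysin, rose 8.75-fold, by 3.13 (SE 0.49), from 7.65 ± 1.14 to 10.77 ± 0.33. Mmp12, an elastase that is also on the trophoblast list, rose 3.19-fold, by 1.68 (SE 0.36, adjusted p = 0.0384), and Mmp15 by 0.86 (SE 0.16). The call of Mmp12 was lost without ambient replicate 2 or any 1 hypoxia array, with adjusted p up to 0.0935, and with no variance trend (0.0507) or a robust trend (0.0706), that of Mmp10 without ambient replicate 3 (0.0611; its rise was 3.78 without ambient replicate 1), and that of Mmp15 without any 1 ambient array or hypoxia replicate 3 (up to 0.105). Collagens and other matrix genes had 3 rises (Nid1 by 0.42, Fn1 by 0.18 and Lamb1 by 0.61), 0 falls and 27 members that did not pass, and adjusted over the list alone 6 were higher and 1, Col6a3, lower. Nid1 (second probe set 0.041) and Lamb1 are basement membrane genes, and both lost their calls without any 1 array but hypoxia replicate 3 (adjusted p up to 0.0899 and 0.116), Fn1 without any 1 array (up to 0.118). With all 6 arrays Fn1 lost its call with quantile normalization (0.0549), no variance trend (0.139) and the replicate block (0.0556), Lamb1 with quantile normalization (0.0509) and no variance trend (0.056), and Nid1 with no variance trend (0.055). This list's upward call (camera adjusted p = 0.0237; adjusted p = 0.558 with an estimated correlation) was lost without ambient replicate 3 (adjusted p = 0.312) and without hypoxia replicate 1 (0.202) and with fry (0.286), and it ranged from 6.53e-04 to 0.558 over the alternatives.

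Endothelial genes had the smallest camera p of the 26 lists. Of 23 measured, 13 rose, 0 fell and 10 did not pass, and adjusted over the list alone 17 were higher. Vwf, which carries clotting factor VIII and tethers platelets, rose 2.29-fold, from 6.97 ± 0.24 to 8.17 ± 0.05. Angpt2, a destabiliser of vessels, rose by 1.79 (SE 0.20), and the receptors Tie1 and Ptprb by 0.69 (SE 0.10) and 0.63 (SE 0.09), with 0.37 and no call at a second probe set of Ptprb. Pecam1 was higher by 0.24 (SE 0.08) and did not pass (adjusted p = 0.131). The list had a median of 0.48 (camera adjusted p = 3.86e-10; adjusted p = 0.15 with an estimated correlation). Angiogenic growth factors and receptors had 6 rises, 0 falls and 20 members that did not pass, with 7 higher and 1 (Nrp2) lower adjusted over the list alone. Members such as Angpt2, Igf2, Nos3 and Tek are shared with the endothelial or trophoblast lists, and Ramp2, part of the adrenomedullin receptor, rose by 0.48 (SE 0.06). Nos3 rose by 0.66 (SE 0.14). Its call was lost without any 1 ambient array, hypoxia replicate 1 or hypoxia replicate 3 (adjusted p up to 0.103). The camera adjusted p of the angiogenic list was 0.0162, with adjusted p = 0.222 with an estimated correlation. Vegfa stood at 9.78 ± 0.10 and 9.75 ± 0.15, a difference of -0.02 with a 95% interval from -0.24 to 0.19. Smooth muscle genes, 21 measured, had 0 calls by limma, with 4 at an unadjusted p under 0.05, and Cald1 (0.27) and Mcam (0.41) had the smallest p. That list did not pass (median 0.10, camera adjusted p = 0.0815) but passed without ambient replicate 1 (median 0.20, 6.92e-04) or hypoxia replicate 3 (0.23, 5.27e-04), with no filter (0.0378), with array weights (0.0154) and with the replicate block (0.0161), over a range from 5.27e-04 to 0.705. Its median was -0.032 without ambient replicate 3, the lowest without any 1 array. Mcam passed without hypoxia replicate 3 (0.0425), with array weights and with the replicate block (range 0.0391 to 0.208), and Cald1 with median centring, the 60% filter, a robust trend, array weights and the replicate block (0.0371 to 0.0496). Acta2 differed by 0.05 (SE 0.17).

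Red cell genes rose as a list. Of 14 members of the erythroid and blood list, 6 rose, 0 fell and 8 did not pass; adjusted over the list alone 9 were higher and 1, Epor, lower. Hbb, the adult beta globin, rose by 1.28 (SE 0.13), from 12.93 ± 0.27 to 14.21 ± 0.16. Alas2, the first enzyme of heme synthesis in red cell precursors, rose 4.92-fold, by 2.30 (SE 0.28), and Ahsp, which stabilises alpha globin, by 1.95 (SE 0.26). Gypc rose by 0.71 (SE 0.13). Hbe1 and Hbz, embryonic globins, were the remaining 2. The list passed (median 0.40, camera adjusted p = 5.17e-04; adjusted p = 0.15 with an estimated correlation). The call of Gypc was lost without any 1 ambient array or hypoxia replicate 1 (adjusted p up to 0.0861), and those of Hbe1 and Hbz as given above. The neutrophil and mast cell list had 3 rises, S100a9 by 1.67 (SE 0.15), S100a8 by 1.38 (SE 0.15) and Kit, the stem cell factor receptor, by 1.43 (SE 0.26), 0 falls and 4 members that did not pass (Cma1, Lcn2, Tpsb2 and Mcpt10). Adjusted over the list alone Cma1 was also higher and Lcn2 lower (-1.93, and -1.11 without hypoxia replicate 3). Its call (camera adjusted p = 0.0421; adjusted p = 0.311 with an estimated correlation) was lost without ambient replicate 2 (adjusted p = 0.0773), hypoxia replicate 1 (0.0503) or hypoxia replicate 3 (0.122), over a range from 0.00767 to 0.311. The call of Kit was lost without ambient replicate 2, ambient replicate 3 or hypoxia replicate 1 (up to 0.0882).

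Uterine natural killer cell genes fell as a group. Of 26 measured, 0 rose, 7 fell and 19 did not pass, and adjusted over the list alone 17 were lower. Cst7, an inhibitor of granule proteases, fell by -0.73 (SE 0.11), Nkg7, a granule protein, by -0.46 (SE 0.07), the interleukin 2 and 15 receptor chain Il2rb by -0.60 (SE 0.10) and the transcription factor Eomes by -0.39 (SE 0.06; a second probe set, at -0.26, did not pass). Perforin (Prf1) was lower by -0.27 (SE 0.09, adjusted p = 0.108) and granzyme B (Gzmb) by -0.20 (SE 0.06, adjusted p = 0.0825), neither past the threshold over all probe sets and both past it adjusted over the list alone (0.0258 and 0.018). The ambient levels of Prf1 and Gzmb were 13.64 ± 0.17 and 14.47 ± 0.05, where the highest values on the arrays were 14.8 to 14.9. Prf1 passed without ambient replicate 1 (0.0409; range over the alternatives 0.0409 to 0.271). The list had a median of -0.33 (camera adjusted p = 2.85e-07; adjusted p = 0.261 with an estimated correlation). The call of Cst7 was lost without ambient replicate 3 (adjusted p = 0.0565), that of Nkg7 without hypoxia replicate 1 (0.0528), that of Eomes without ambient replicate 2, ambient replicate 3 or hypoxia replicate 1 (up to 0.0588), and that of Il2rb without ambient replicate 1, ambient replicate 3, hypoxia replicate 1 or hypoxia replicate 2 (up to 0.0728).

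T and B cell genes fell too as a list, with 0 rises, 5 falls and 6 members that did not pass among 11 measured, and 8 lower adjusted over the list alone. The 5 were Cd3g, by -0.98 (SE 0.21), Cd8a, by -0.90 (SE 0.19), Cd247, by -0.49 (SE 0.09; a second probe set, at -0.52, did not pass), Cd74, the MHC class II invariant chain, by -0.37 (SE 0.07), and Lck, by -0.54 (SE 0.13). Cd247 and Lck are also used by natural killer cells and Cd74 in MHC class II presentation, so the fall need not be one of T and B cells alone. The calls of Cd3g, Cd8a, Cd247 and Cd74 were lost without hypoxia replicate 1 or hypoxia replicate 2 (adjusted p up to 0.134, 0.105, 0.0924 and 0.0877 over the arrays). Ambient replicate 1 had the same effect for Cd3g, Cd8a and Cd247, ambient replicate 2 for Cd8a, Cd247 and Cd74, and ambient replicate 3 for Cd3g, Cd247 and Cd74. The call of Lck was lost without any 1 array but hypoxia replicate 3 (up to 0.137), with no filter (0.0505) and with no variance trend (0.0671). Fcer1g lost its call without ambient replicate 2 or hypoxia replicate 1 (up to 0.0536). The list median was -0.53 (camera adjusted p = 8.56e-06; adjusted p = 0.261 with an estimated correlation). Macrophage and dendritic cell genes had 2 falls, Cd163, a scavenger receptor for hemoglobin, by -1.05 (SE 0.09), and Fcer1g by -0.57 (SE 0.09), 0 rises and 16 that did not pass. When adjusted over the list alone, Clec10a was also lower and Gpnmb higher, and Cd68 differed by -0.06 (SE 0.09). This list passed downward (median -0.22, camera adjusted p = 4.19e-04; adjusted p = 0.301 with an estimated correlation). Interferon response genes had 2 falls, the class II gene RT1-Da by -0.45 (SE 0.06) and the immunoproteasome subunit Psmb8 by -0.60 (SE 0.14), 0 rises and 25 that did not pass. Irf1 and Psmb9 were lower too when adjusted over the list alone, and the call of Psmb8 was lost without any 1 array but hypoxia replicate 3 (up to 0.135) and with no variance trend (0.0608). The call of the interferon list (camera adjusted p = 0.00137; adjusted p = 0.558 with an estimated correlation) was lost without ambient replicate 3 (adjusted p = 0.296), without hypoxia replicate 2 (0.0765) and with fry (0.362), over a range from 5.19e-05 to 0.558.

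Uterine and glandular epithelium genes were lower as a list by camera (median -0.36, adjusted p = 6.50e-04), a call that was lost with an estimated correlation (adjusted p = 0.301) and with fry (0.0672). Of 11 measured, 0 rose, 2 fell and 9 did not pass, and adjusted over the list alone 6 were lower. The 2 were the adhesion genes Epcam, by -1.77 (SE 0.38), from 8.54 ± 0.41 to 6.77 ± 0.81, and Cdh1, by -1.07 (SE 0.25). Cldn10, a tight junction protein outside the list, fell by -1.74 (SE 0.34), and Slc34a2, an epithelial phosphate transporter, by -1.21 (SE 0.27). The calls of Epcam, Cdh1, Cldn10 and Slc34a2 were lost without any 1 ambient array or hypoxia replicate 2, and those of the first 3 without hypoxia replicate 3, with adjusted p up to 0.123, 0.154, 0.0892 and 0.135. With all 6 arrays Epcam lost its call with a robust trend (0.0579) and array weights (0.0613), Cdh1 with these (0.05001 and 0.0785) and no variance trend (0.0596), and Slc34a2 with array weights (0.0576) and no variance trend (0.0545). Yolk sac and fetal liver genes, with 6 measured, had 0 calls by limma and 0 at an unadjusted p under 0.05, with Fgg at -0.87 (past the threshold with the replicate block, 0.00872) and Rbp4 at -0.37. The list did not pass (camera adjusted p = 0.102) except without hypoxia replicate 3 (0.036), with no filter and with the replicate block, over a range from 0.0218 to 0.379.

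Decidual stroma genes moved both ways, with 4 rises, 1 fall and 19 members that did not pass among 24. Hsd17b2, which inactivates estradiol, rose by 1.69 (SE 0.17), the transcription factor Hand2 by 0.64 (SE 0.07), Bmp8a by 0.44 (SE 0.09) and Bmp2 by 0.91 (SE 0.20). Tdo2, the tryptophan dioxygenase of decidua, fell by -1.18 (SE 0.24). The calls of Tdo2 and Bmp8a were lost without any 1 array but hypoxia replicate 1 (adjusted p up to 0.0985 and 0.104), and that of Bmp2 without any but ambient replicate 1 (up to 0.131) and with no variance trend (0.0502). There were 7 higher, adjusted over the list alone, and 3 (Tdo2, Igfbp1 and Pdgfra) lower. Prl8a2, the decidual prolactin, was higher by 1.73 (SE 0.46, adjusted p = 0.0683; second probe set 2.24, not past the threshold), with 13.24 ± 1.10 in hypoxia, and passed without hypoxia replicate 2 (2.36, adjusted p = 0.00322), with array weights (0.0212) or with the replicate block (0.029; range over the alternatives 0.00322 to 0.191). The list did not pass (camera adjusted p = 0.0664), but passed without ambient replicate 1 (0.00507) or ambient replicate 2 (0.0479), with offsets of 16 (0.0314) and 64 (0.0324), with no filter (0.00425) and with fry (0.027), over a range from 0.00425 to 0.347. Steroid and lipid metabolism genes had 7 rises, 0 falls and 12 that did not pass among 19, with 9 higher and 1 (Plin2) lower adjusted over the list alone. The sterol enzymes Cyp51 and Sqle rose by 0.49 (SE 0.07) and 0.45 (SE 0.08), and the lipid regulator Pparg by 0.97 (SE 0.16). The call of Sqle was lost without any 1 ambient array or hypoxia replicate 1 (up to 0.0788). That list passed upward (median 0.22, camera adjusted p = 7.62e-05; adjusted p = 0.15 with an estimated correlation).

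Targets of the hypoxia-inducible factors (HIF) did not shift as a list. Of 28 measured, 4 rose, 0 fell and 24 did not pass. The prolyl hydroxylases of collagen P4ha1 and P4ha2 rose by 0.45 (SE 0.06) and 0.42 (SE 0.08), and the mitophagy genes Bnip3 and Bnip3l by 0.35 (SE 0.06) and 0.32 (SE 0.07). There were 6 higher, adjusted over the list alone, and 3 (Bhlhe40, Selenbp1 and Ankrd37) lower. The list median was 0.01, its mean -0.0026 and the camera direction upward (adjusted p = 0.477; adjusted p = 0.758 with an estimated correlation). Slc2a1, Ldha and Kdm3a differed by 0.03 (95% interval -0.17 to 0.23), -0.11 (-0.29 to 0.06) and -0.08 (-0.29 to 0.12). Hif1a and Epas1, the factors themselves, differed by 0.06 (-0.07 to 0.19) and 0.05 (-0.05 to 0.14), and a second probe set of Epas1 by -0.078. In the list of hypoxia sensors and chromatin regulators, Arnt2 rose by 0.67 (SE 0.12), 0 fell and 15 of 16 did not pass, while Cited2 and Egln1 were also higher, and Arnt lower, adjusted over the list alone. Its median was -0.08, its mean 0.01 and its camera direction downward (adjusted p = 0.927). Glycolysis genes had 1 rise (Slc16a3, a lactate exporter, by 0.49, SE 0.09), 0 falls and 15 that did not pass, with Pfkl and Eno2 also higher and Pfkm lower adjusted over the list alone (camera adjusted p = 0.737). Oxidative phosphorylation genes had 0 calls by limma among 26, with 4 at an unadjusted p under 0.05, Uqcrfs1 at -0.16 and Atp5f1a at -0.15 (camera adjusted p = 0.15). The calls of P4ha1, P4ha2, Bnip3, Bnip3l, Arnt2 and Slc16a3 were all lost without ambient replicate 3, with adjusted p over the arrays of up to 0.0502, 0.0805, 0.0761, 0.146, 0.0963 and 0.0925. Ambient replicate 1 had this effect for P4ha2, Bnip3l and Arnt2, ambient replicate 2 for Bnip3, Bnip3l, Arnt2 and Slc16a3, hypoxia replicate 1 for P4ha2, Bnip3l and Slc16a3, hypoxia replicate 2 for P4ha2, Bnip3, Bnip3l and Arnt2, and hypoxia replicate 3 for Arnt2. Bnip3l also lost its call with quantile normalization (0.0522), no filter (0.0541) and no variance trend (0.0718). Second probe sets of Arnt2 (-0.13), P4ha2 (0.066) and Bnip3l (0.13) differed from those given.

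Proliferation and ribosomal protein genes shifted downward by small amounts. Of 30 proliferation genes, 0 rose, 1 fell (Kif20a, a mitotic kinesin, by -0.42, SE 0.09) and 29 did not pass, while 27 had lower means in hypoxia. By limma 0 passed adjusted over the list alone, with 10 at an unadjusted p under 0.05. The call of Kif20a was lost without any 1 array but hypoxia replicate 3 (up to 0.127), and with all 6 arrays with no filter (0.0505), no variance trend (0.0516) and the replicate block (0.0571). The list median was -0.24 (camera adjusted p = 3.38e-05; adjusted p = 0.486 with an estimated correlation and 0.269 with fry), and it was -0.12 without hypoxia replicate 2 and -0.33 without hypoxia replicate 3. Of 24 ribosomal protein genes 0 passed by limma, 8 had an unadjusted p under 0.05 and 22 had lower means, with Rps3 at -0.16 (past the threshold with quantile normalization, the 60% filter and array weights, 0.0406 to 0.044) and Rpl24 at -0.15. That list passed (median -0.07, camera adjusted p = 1.12e-04; adjusted p = 0.311 with an estimated correlation).

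Cytokine genes moved in both directions. Of 26 cytokines, chemokines and receptors, 5 rose and 1 fell (Csf1, by -0.26, SE 0.06), and 20 did not pass. Tgfb3 rose by 0.85 (SE 0.09), from 10.94 ± 0.10 to 11.79 ± 0.17, Il1b by 0.57 (SE 0.08), Ccl3 by 0.53 (SE 0.10), Tgfb2 by 0.52 (SE 0.11; a second probe set, at 0.30, did not pass) and the decoy receptor Il1r2 by 0.65 (SE 0.15). The calls of Ccl3 and Tgfb2 were lost without any 1 ambient array or hypoxia replicate 2 (adjusted p up to 0.0797 and 0.107), that of Ccl3 also without hypoxia replicate 3 and that of Tgfb2 without hypoxia replicate 1. That of Csf1 was lost without any 1 array (up to 0.139), with an offset of 64, no filter, no variance trend and the replicate block (0.0501 to 0.0837), and that of Il1r2 without any 1 ambient array or hypoxia replicate 1 (up to 0.139) and with no variance trend (0.056). There were 6 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.674). Among 20 immediate early genes, Fos rose by 0.74 (SE 0.17), while a second probe set of it differed by -0.01, and Egr1 and Egr2 fell by -0.63 (SE 0.09) and -0.94 (SE 0.20). The other 17 did not pass, and the same 1 and 2 passed adjusted over the list alone (camera adjusted p = 0.102, and 0.0452 with the 60% filter). Of 28 stress and unfolded protein response genes, Hsp90b1 rose by 0.19 (SE 0.05), Herpud1 fell by -0.38 (SE 0.08) and 26 did not pass. Mt1, Ddit3 and Calr were higher as well when adjusted over the list alone (camera adjusted p = 0.23). The call of Hsp90b1 was lost without any 1 array (adjusted p up to 0.155), and with all 6 arrays with quantile normalization (0.108), no filter (0.062), no variance trend (0.132) and the replicate block (0.0663). That of Herpud1 was lost without any but hypoxia replicate 1 (up to 0.124) and with no variance trend (0.054), that of Fos without any but hypoxia replicate 2 (up to 0.136) and with quantile normalization, an offset of 64, no filter or no variance trend (0.0501 to 0.0625), that of Egr2 without ambient replicates 2 or 3 or hypoxia replicates 1 or 2 (up to 0.117), and that of Egr1 without ambient replicate 3 (0.0544).

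**Figure D2:**
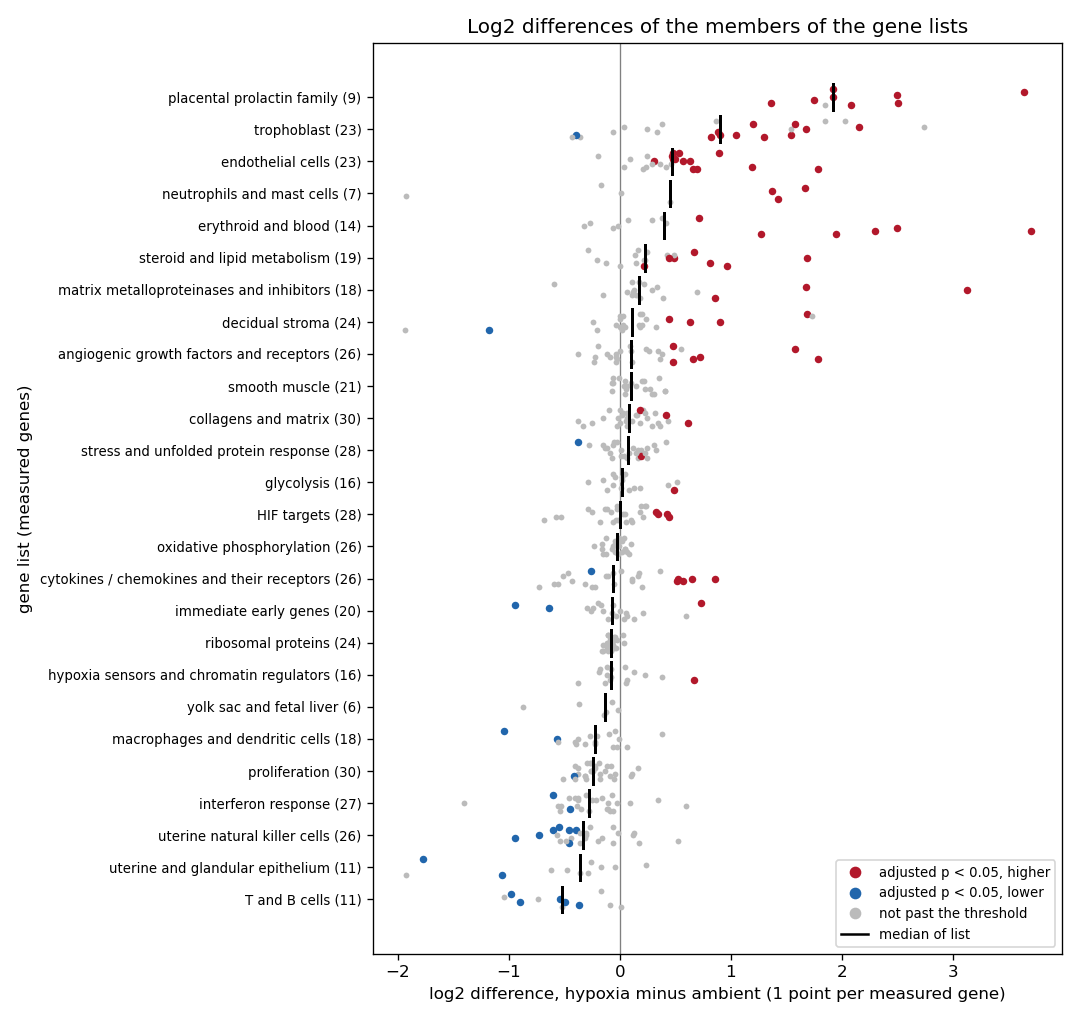
Log2 differences, hypoxia minus ambient, of the measured members of the 26 gene lists, 1 point per gene (red or blue past the threshold, grey not past it), with a black bar at each list's median and the number of measured genes in brackets. Medians ranged from -0.53 for T and B cells to 1.93 for placental prolactins, and the HIF target list lay at 0.01.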

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

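The tests of explanations in this part were chosen after the results were seen, while the fits without 1 array, with other scalings and without the filter that some of them draw on were planned. The 12417 probe sets left out for low means had no part in the main comparison. Among them a fit without the filter called 137, 87 higher in hypoxia and 50 lower. Single genes were searched for among the rises only. Of called genes whose groups did not overlap and whose hypoxia mean reached the median of all probe sets, 1 was found, Ptgs2, the inducible cyclooxygenase. It was higher by 1.64 (SE 0.26), at 4.89 ± 0.37 in ambient, where the arrays' highest bacterial controls lay between 4.89 and 4.94, and 6.53 ± 0.51 in hypoxia (limma adjusted p without the filter 0.014), and the call was lost without ambient replicate 3 (1.45, 0.0578).

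The count of 1116 called probe sets was set against the other splits of the 6 arrays into 3 and 3. The real split was 1 of 10 and the highest count in any other was 0. With 10 splits the share cannot go below 0.1, so these splits are too few to decide on chance.

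The first pattern weighed is the joint rise of the trophoblast and placental prolactin lists. On ambient replicate 3 Prl5a1, Prl7a3, Prl7b1 and Prl8a9 lay lowest in their group. A difference set by this array is argued against, since without it the prolactin list still rose by a median of 1.39. The trophoblast list rose by a median of at least 0.82 without any 1 array. Placental tissue carried over in the dissection cannot be told apart from more trophoblast within the gland. Of 9 placental transcripts on the array, from a list of 12 chosen after the rise was seen, the median change was 0.025. That median was the value of Phlda2, which lay at background, so it does not speak against carried-over tissue. Without the filter Prl3b1, itself on the prolactin list, passed (1.36, limma adjusted p = 0.0272). Ctsq did not (1.85, 0.0578), though it passed in the filtered fit without ambient replicate 3 (1.23) or with an offset of 64. Tpbpa did not pass either (0.65, 0.0733), except without hypoxia replicate 2 (0.0352). Slc16a1 (-0.15) and Tfeb (-0.070) did not pass. Peg10 (-0.046), Phlda2 (0.025), Gcm1 (-0.021) and Psg16 (0.25) had means below the highest bacterial control in both groups. With the filter the call of Prl3b1 (adjusted p = 0.0309) was lost without any 1 array but hypoxia replicate 2 (up to 0.111). The embryonic globins were not on this list. Hbe1 stood at 8.89 to 9.92 on the hypoxia arrays and 7.98 on ambient replicate 2, against 4.76 and 4.58 on the other ambient arrays. Whether it came from carried-over tissue was not tested. More or more active invasive trophoblast under low oxygen stays open as a biological explanation that was not tested.

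The second pattern is the fall of the natural killer cell and T and B cell lists. If added red cells and trophoblast had merely diluted the tissue, other cell types would have fallen alike. The smooth muscle median lay 0.43 above that of the natural killer cell list (95% bootstrap interval over members 0.28 to 0.64). The decidual stroma median lay 0.45 above it (0.26 to 0.63) and the endothelial median 0.81 above it (0.60 to 0.94). The endothelial list had already been seen to rise, and the decidual stroma list held 4 rises and 1 fall, so neither is an unmoved reference. The smooth muscle list held 0 calls. In these 6 arrays its median argues against an even dilution as the whole cause, within the limits of the intervals given below. The macrophage and dendritic cell median (0.11 above that of the natural killer cell list, -0.080 to 0.31) and the T and B cell median (-0.19, -0.58 to 0.19) were not separated from it. The bootstrap intervals of this paragraph treat the genes of a list as independent and leave out the spread between arrays. They are too narrow, since the correlation estimated by camera was 0.61 in the smooth muscle list and 0.19 in the natural killer cell list. Without 1 array the smooth muscle median lay 0.27 to 0.63 above that of the natural killer cell list, with 6 of 6 intervals above 0. These fits share most of their arrays, so they are not separate tests. The smooth muscle median itself was -0.032 without ambient replicate 3. Scaling between arrays moves genes of the same level alike. Set against the 200 other probe sets nearest in level, the natural killer cell list still lay at a median of -0.328 (95% bootstrap interval over members -0.46 to -0.15). The T and B cell list lay at -0.52 (-0.88 to -0.15). Those near probe sets had median changes of 0.012 and -0.014, so the values nearly repeat the list medians. The fall was thus not shared by genes of the same level. With arrays that already shared a scale this was largely set in advance and does not decide on scaling. A shift of most genes at once that the authors' scaling took out cannot be told apart from none, since the deposited arrays already shared a scale and scaling them again (-0.34) decides nothing. Fewer of these cells, or lower expression per cell, may both give this fall and cannot be separated in whole tissue.

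The third pattern is the absence of a shift in the HIF target list. Within the spread between these arrays, low precision is argued against as the reason for missing rises of 1.5-fold or more in array signal. Of the 28 measured targets, 26 had a 95% interval that left out such a rise, the exceptions being P4ha1 and P4ha2. Each interval holds for a single gene and was not adjusted over the 28. If the replicates were not separate animals, the intervals leave out the spread between animals and are too narrow. How far the summary compressed folds is not known. The intervals do not decide on smaller rises, such as those called for Bnip3 (0.35) and Bnip3l (0.32), which count among the 26. A HIF response that had faded by the end of the exposure, or an oxygen level in the tissue that differed less than that of the air, stays open and was not tested.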

How the results depend on the processing

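All alternatives were planned. The 87 named genes past the threshold kept their direction in every alternative that measured them, and 33 kept their call in all of them; 54 lost it without at least 1 array, which leaves fewer samples. Of these 54, 19 also lost it with all 6 arrays, 16 with no variance trend, 9 with a robust trend, 5 with quantile normalization, 5 with array weights, 4 with no filter, 3 with the replicate block and 1 with an offset of 64 (adjusted p up to 0.139). The 16 lists past the threshold kept their direction throughout. With the estimated correlation 0 of them passed (5 of the 26 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.15), and with fry 12 of them did; collagens, epithelium, proliferation and interferon response lost their calls and decidual stroma passed, 13 lists in all. The count of 1116 differing probe sets was 2228 at an adjusted p of 0.10 (1334 higher, 894 lower). It ranged from 270 to 1006 when 1 array was left out, with 226 to 666 higher and 44 to 340 lower, and the number at least 1.5-fold from 202 to 505. Without the variance trend 241 probe sets were lower, and with the offset of 64, which compresses low signals by construction, 288 differed by at least 1.5-fold in place of 448. Other causes were not tested. Genes and lists with too few members left by the 60% filter have no value there. Only results that had not passed turned. The direction of the test turned for the HIF targets without hypoxia replicate 3 (median -0.064; range of medians without 1 array -0.064 to 0.052). It turned for the hypoxia sensors with no filter (median -0.082), with fry (-0.083) and without ambient replicate 2 or hypoxia replicate 1 (range without 1 array -0.069 to -0.034), and for the cytokines with fry (-0.057), while these medians stayed negative. Without single arrays Acta2 ranged from -0.049 to 0.23, Cd68 from -0.15 to 0.016, Slc2a1 from -0.060 to 0.10 and Vegfa from -0.10 to 0.050. Quantile normalization, median centring and the offsets turned no list or named gene. The replicate block gave 1317 probe sets (797 higher, 520 lower). Arrays of the same number deviated from their group means with correlations of 0.01, 0.07 and 0.07, so the numbers are not taken to pair them. Low signal limits the folds of genes near the bacterial controls, as for Elovl2, and the brightest, such as Gzmb at 14.5, sit close to the highest values on the arrays (14.8 to 14.9).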

Other observations

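The lists and tests of this part were chosen after the data were seen. Among imprinted genes, H19, a noncoding RNA of the Igf2 locus, was higher by 1.69 (SE 0.22, limma adjusted p = 0.00966), Meg3 by 1.02 (SE 0.07, adjusted p = 0.00166) and Ascl2, a trophoblast regulator, by 0.82 (SE 0.15, adjusted p = 0.0242), beside Igf2 and Cdkn1c. The call of Ascl2 was lost without ambient replicates 2 or 3 or hypoxia replicates 1 or 2 (up to 0.0917). The hypothesis that imprinted genes are higher as a class could not be decided. Without H19, Igf2, Cdkn1c and Meg3, which prompted it, a list of 26 imprinted genes with 11 measured had a median of 0.08 and a camera p of 0.19 (0.31 with an estimated correlation), and Ascl2 was its 1 called member.

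Of 23 measured genes of epithelial junctions and polarity, 5 of them also on the epithelium list (Epcam, Cdh1, Cldn3, Cldn7 and Elf3), 11 fell, 9 of these outside that list, and 1, Krt8, which trophoblast also expresses, rose, with Dsg2 at -0.78 (SE 0.11), Ppl at -0.80 (SE 0.15) and Perp at -0.91 (SE 0.21). The call of Ppl was lost without ambient replicates 1 or 3 or hypoxia replicates 2 or 3 (up to 0.0938), and that of Perp without any 1 array but hypoxia replicate 1 (up to 0.153), with no variance trend (0.056) and with array weights (0.0629). MHC class II presentation genes had 3 falls (RT1-Da, Cd74 and Ifi30) among 11 measured, with a median of -0.34, and the first 2 are also on the interferon and the T and B cell lists. The call of Ifi30 was lost without any 1 array (up to 0.134), with no filter, no variance trend and the replicate block (0.0541 to 0.0839). Genes of heme synthesis and red cell metabolism had 6 rises among 19, of which Alas2 and Ahsp are also on the erythroid list, among the others Ampd3 (1.34), Bpgm (0.92), which makes the regulator of oxygen release 2,3-bisphosphoglycerate, and Fech (0.88), the last enzyme of heme synthesis, whose call was lost without ambient replicates 2 or 3 or hypoxia replicate 1 (up to 0.0808). These lists were built around genes already seen to differ, so their camera adjusted p of 3.75e-07, 2.29e-05 and 7.10e-05 are not independent evidence, and with an estimated correlation the adjusted p were 0.128, 0.0658 and 0.128.

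Hbe1, Hbg1 and Hbz did not follow Hbb, the adult beta globin, across ambient arrays. Hba-a3 was highest on replicate 2 as well, though by little (10.24, against 10.19 on replicate 1 and 9.76 on replicate 3). Hbe1, Hbg1 and Hbz stood at 7.98, 6.62 and 7.07 on ambient replicate 2, against 4.76, 4.39 and 4.96 on replicate 1 and 4.58, 4.37 and 4.63 on replicate 3, while Hbb stood at 12.77 on replicate 2, 13.25 on replicate 1 and 12.78 on replicate 3.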
